A study of Homo sapiens with 16 samples.

How the data were processed

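Total RNA from 16 human T-ALL cell lines was hybridised to 1 Affymetrix U133 Plus 2.0 array per line, after 24 hours of culture at equal density per the labels. The deposited values are probe set intensities on a linear scale. The software, the background correction and the scaling that the authors used are not given in the sources used here. The table held 54675 values per array, from 0.6 to 24485, with between 494 and 583 values of exactly 1 on each array. Array medians ranged from 37.6 to 45.0 and upper quartiles from 247.8 to 308.4, and no further normalization was applied. No line was measured more than once, no column was left out, and 0 pairs of columns were mostly identical. The number of arrays limits the precision of each comparison.

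Values were analysed as log2(intensity + 16). Of the probe sets, 62 were controls, 41097 were listed with 1 gene, 1801 with several genes and 11715 were unlisted in the annotation used. Of those with 1 gene, 41043 matched a symbol of the reference annotation, with 0 symbols updated. Each of 19740 genes was represented by the probe set with the highest mean over the 16 arrays among those naming only that gene. Control probe sets served as technical measures. The 9 hybridisation spike probe sets had a median SD over arrays of 0.13 and a largest of 0.17, and the 12 poly-A spike probe sets a median SD of 0.23. The ratio of the 3' to the 5' control probe set ran from 1.44 to 2.03 for ACTB and from 0.904 to 1.05 for GAPDH.

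All lines belonged to 1 group, so no groups were compared. The gene lists, relations, tests, named-gene rule and first set of alternatives were fixed before the data were examined. There were 26 lists with 305 different genes, of which 272 were measured and 33 were not analysed here, and 25 lists had at least 5 measured genes. The other list was not used here. The lists covered T-ALL transcription factors, TAL1 partners and targets, T-cell stages and receptors, signalling, metabolism and stress, tumour suppressors, and markers of other cell types. The text names at most the 6 members of each list with the largest range, every transcription factor, the 15 genes with the highest SD, at most 3 genes set apart high and 2 set apart low per line, members of the relation families, and the 10 genes with the smallest p in each direction of a driver fit. Names outside this rule are stated as such, and members called in a list test are named in full where they are few.

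A list's median SD and its median pairwise Pearson r were ranked among 10000 random lists of the same size, matched on mean expression in 20 bins. A list was called wide at percentile 95 or above, narrow at percentile 5 or below and co-varying at percentile 95 or above. A list value is the mean over its genes of the log2 value centred on the gene's mean, without the partner gene and without genes shared by both lists compared. A measure split the lines where its largest gap reached the share of the range fixed for it, namely the third part, with at least 3 lines on each side. Relations were then tested only within sets of at least 6 lines, and where the second measure split, as in 3 planned pairs, no r is given. Of 24 planned pairs 3 were not analysed here because a gene was not measured. Pearson's r and Spearman's rho each had a two-sided permutation test, with 100000 resamples and a smallest p of 1e-05 for 9 or more lines. For 8 or fewer lines all orders were enumerated, an exact test that replaced the resampling first planned and changed no call. Adjusted p-values follow Benjamini and Hochberg within a family.

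Genes following the level of LYL1, MYC or TAL1 were found with limma 3.58.1 (trend and robust) in R 4.3.3, at an adjusted p below 0.05, among genes whose 3rd highest value lay above the table median (13306 with the driver left out). A further planned driver was not analysed here. Each count was compared with 100 permutations of the driver levels. Genes were set apart high where the highest line lay at least 3 log2 units above the next, and low where the lowest lay at least 2 below the next and the next was above the table median. Principal components used 13307 genes. Other steps used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, with the random seed 1.

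The methods were tested on simulated data with the same number of lines, in which 200 genes followed the driver. At slopes of 0.5 and 1.0, limma recovered 77.0% and 93.0% of them for LYL1, 81.0% and 96.9% for MYC, 17.0% and 65.0% for the lines with high TAL1, and 0.0% and 0.0% for those with low TAL1, with 6, 9, 4 and 0 false calls. The limma simulation drew normal noise independently for each gene, so genes with 1 outlying line and genes varying together were not simulated. Its false calls therefore do not measure those that such genes can cause. A simulated co-varying list reached percentile 100 and 0 of 24 others were called. In that simulation each gene was shuffled over the lines independently, which removed shared variation between genes. False calls of the list test under such variation were therefore not measured. The relation test called 97 of 100 related and 3 of 100 unrelated pairs.

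Alternatives covered the added constant (1 and 64), quantile normalization, centring of arrays, the mean of all probe sets or the one with the highest SD, leaving out probe sets ending in _x_at, filters on low values, rank correlation, a plain variance model, thresholds, and leaving out lines. The line sets with high and low values of a measure were held fixed across alternatives. Neighbouring genes were placed in the order of the reference annotation for 1 test. Levels of genes on the Y chromosome and of genes that mark the sex of a line were not used here.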

Results

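Total RNA of 16 human cell lines of T-cell acute lymphoblastic leukemia (T-ALL), a cancer of immature T cells, was measured with 1 Affymetrix U133 Plus 2.0 array per line. Each culture was grown without treatment and harvested after 24 hours. All lines formed 1 group without a control, and no line was measured more than once. Values are therefore given per line without a replicate error, and every SD describes the spread between different lines. The arrays held 54675 probe sets each, and their median intensity ranged from 37.6 in MOLT-16 to 45.0 in LOUCY. Intensities are given on the deposited linear scale, on which the median of the whole table was 42.3, and SDs and ranges are in units of log2(intensity + 16). The number of arrays limits the precision of every comparison.

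The first question was which T-ALL transcription factor genes each line expressed. TAL1, a basic helix-loop-helix factor often activated in T-ALL, split the lines: its intensity was 3586 in JURKAT, 1362 in MOLT-4, 1317 in HSB-2, 1029 in PF-382, 869 in SUP-T13, 813 in CCRF-CEM, 499.5 in SKW-3 and 425 in MOLT-16. The other 8 lines lay between 14.7 and 48.5. DU528 held the highest of these 8 values, yet a second TAL1 probe set read 373.6 in DU528, its highest value in any line, against 272.6 in JURKAT. Of the homeobox genes, TLX1 reached 2192 in ALL-SIL and at most 47.1 elsewhere, and NKX2-5 reached 1300.2 in CCRF-CEM, 1054 in PEER and 787 in MOLT-16 and at most 18.0 elsewhere.

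**Figure D1:**
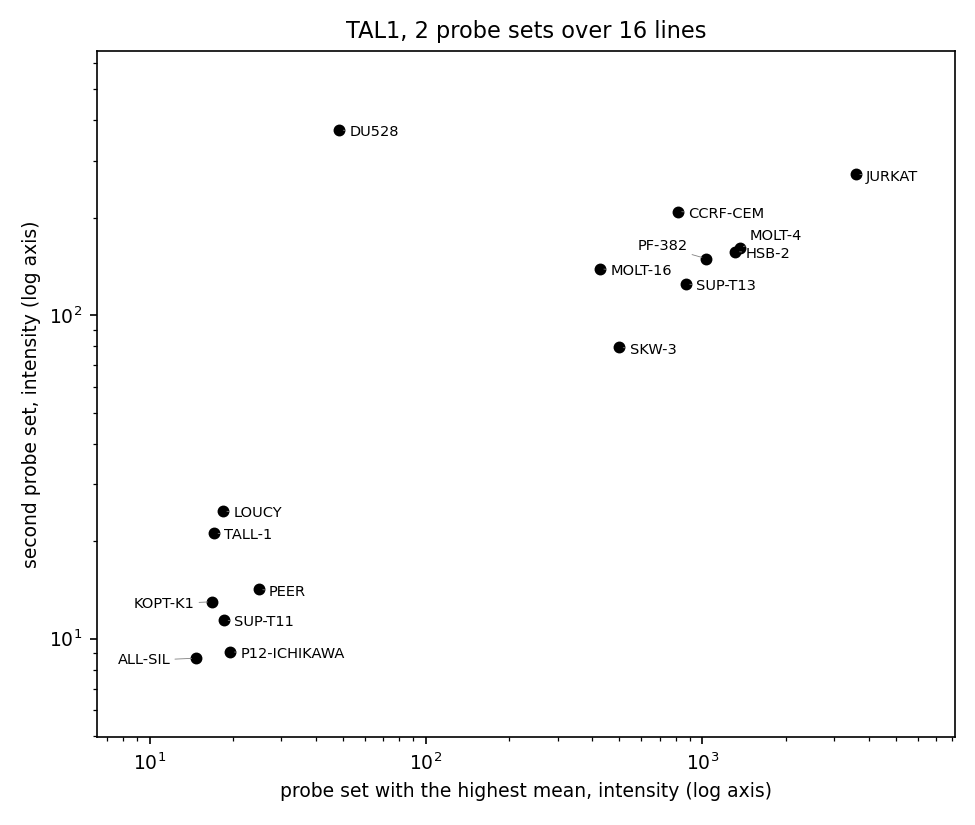
Intensity of 1 TAL1 probe set against another (both axes logarithmic), 1 point per line. DU528 reads 48.5 on the probe set used for TAL1 and 373.6 on the second, away from the trend of the other 15 lines.

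LMO2, a partner of TAL1 in a DNA-binding complex, was highest in P12-ICHIKAWA (6805) and KOPT-K1 (5946), followed by DU528 (3296) and LOUCY (2327). It lay between 8.7 and 17.4 in SUP-T11, JURKAT, TALL-1 and ALL-SIL. LOUCY and DU528 also had the highest LYL1 (3655 and 2178), MEF2C (4433 and 927) and MYCN (4138 and 5120.4). MYC, a driver of cell growth, lay between 3638 and 9554 in 15 lines and at 23.6 in LOUCY. MYB lay between 5269.9 and 11422 in 15 lines and at 230.2 in SUP-T11, which also had the lowest ZEB1 (839, against 3529 in TALL-1). LMO1 was 133.4 in JURKAT and at most 41.5 elsewhere. The other 8 factors stayed low in every line: TAL2, NKX2-2, LMO3, SPI1, TLX3 and OLIG2 at or below 39.6, BHLHE22 at or below 72.8 and NKX2-1 at or below 104.3. Of the 19 measured factors, 9 had an SD above 1, and 9 never reached 4 times the table median.

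**Figure D2:**
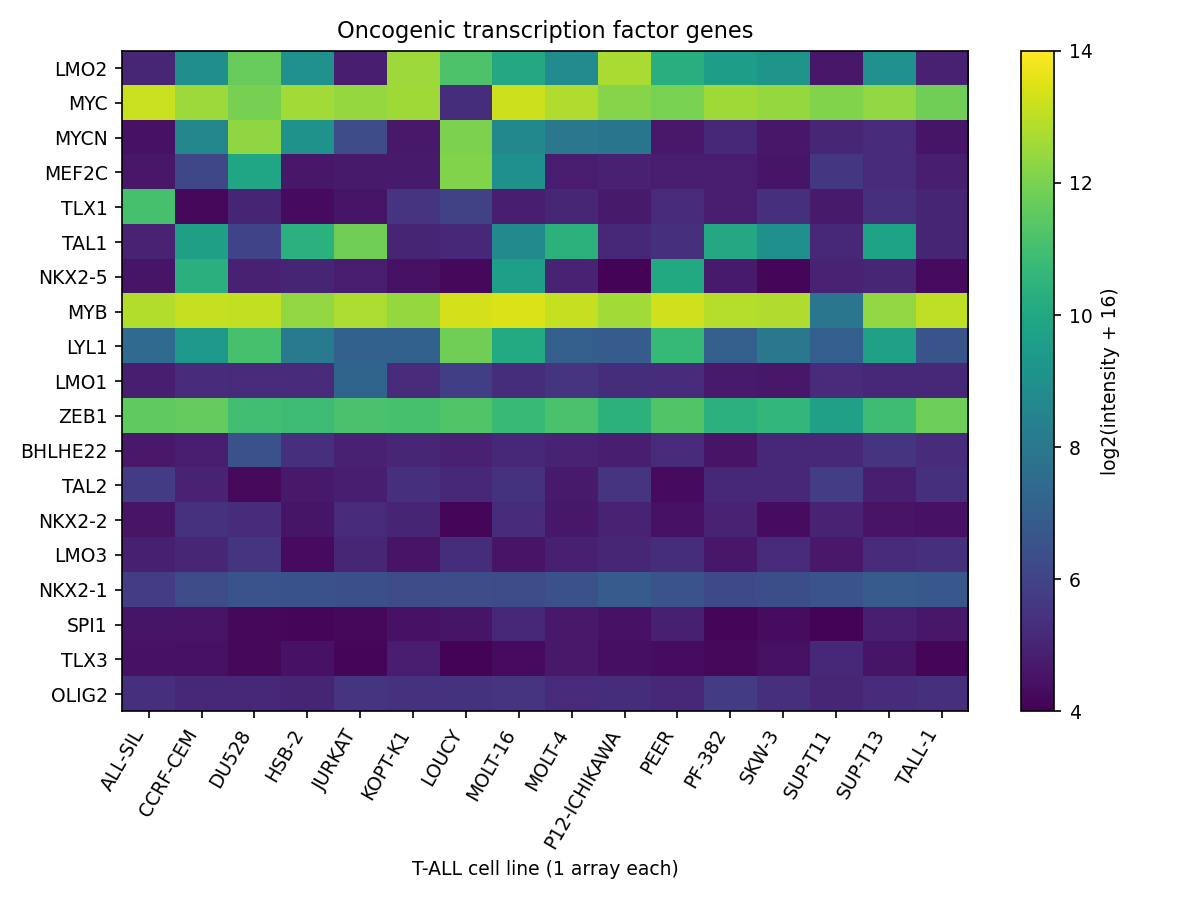
Heat map of 19 T-ALL transcription factor genes (vertical axis) in the 16 lines (horizontal axis), coloured by log2(intensity + 16). TAL1 is high in 8 lines, TLX1 in ALL-SIL, NKX2-5 in 3 lines, and MYC is low in LOUCY.

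Genes of immature and of cortical thymocytes, which mark stages of T-cell development, differed widely between lines. Of the CD1 genes, which encode surface molecules of cortical thymocytes, CD1B was at most 15.1 and CD1E at most 6.5 in DU528, MOLT-16, SUP-T11, LOUCY, PEER and HSB-2. The highest values were 9328 for CD1B in P12-ICHIKAWA, 8796 for CD1E in MOLT-4, and 4276 for CD1A and 2933 for CD1C in PF-382. RAG1, part of the recombinase, was 3415 in CCRF-CEM and 7.0 in HSB-2, and DNTT, a polymerase of receptor gene joining, was 13597 in PEER and 40.5 in MOLT-16. Among progenitor genes, GATA2 was 3946 in LOUCY and 3049.7 in DU528, IGFBP7 was 5307 in DU528, 2247 in LOUCY and 1344 in HSB-2, and KIT, the receptor for stem cell factor, was 3613 in HSB-2, 2608 in PEER, 2403 in DU528 and 2219 in SUP-T13. CD44 was 8144 in DU528 and 10.2 in JURKAT.

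Of the 12 cortical genes 9 had an SD above 1, as had 13 of the 17 immature genes, of which 5 never reached 4 times the table median. The mean of the centred cortical genes was highest in CCRF-CEM (2.21) and lowest in DU528 (-2.22), and that of the immature genes was highest in DU528 (2.40) and LOUCY (2.14). Both lists varied more than 10000 random lists matched on expression, with a median SD of 2.37 for the cortical and 1.75 for the immature genes, each at percentile 100. Their members also varied together, with a median pairwise r of 0.464 and 0.202 (both at percentile 100). The ratio of the 3' to the 5' ACTB control probe set, a measure of RNA integrity, was lowest in DU528 (1.44) and highest in MOLT-4 (2.03). In two-sided permutation tests over 25 lists it related to the cortical list with r = 0.653 (p = 0.00745, adjusted p = 0.089; rho = 0.668, p = 0.00573; r = 0.554 without JURKAT and MOLT-4). It related to the immature list with r = -0.612 (p = 0.0107, adjusted p = 0.089; rho = -0.668, p = 0.00607; r = -0.615 without the same pair).

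Genes of the T-cell receptor complex were lowest in MOLT-16 or DU528 in several cases. CD3E was 31.2 in MOLT-16 and between 227 and 391 elsewhere, CD3G was 667 in DU528, 1472 in MOLT-16 and 8568 in KOPT-K1, and the kinase LCK ran from 942 in MOLT-16 to 14199 in HSB-2. The adaptor LAT was 139 in MOLT-16 and 4024 in HSB-2. Only 2 of the 10 members had an SD above 1. The median SD was 0.78 and the median pairwise r 0.391, both at percentile 100. Surface antigens spread more, with an SD above 1 in 10 of 12 genes and a median SD of 1.86 (percentile 100; median r 0.207, at 99.9). CD2 was 11.1 in DU528 and 5051 in SKW-3, CD8A was 8.2 in LOUCY and 3841 in KOPT-K1, CD5 was 9.5 in DU528 and 2421 in SUP-T11, and CD52 was 87.0 in MOLT-16 and 10816 in SUP-T11. MOLT-16 had the lowest list value for both groups (-1.64 and -2.33).

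NOTCH1 pathway genes were highest in TALL-1 and KOPT-K1, with list values of 1.78 and 1.39, and lowest in SUP-T11 (-1.75). NOTCH3, a receptor of the pathway, was 3955 in TALL-1, 2025 in ALL-SIL and at most 23.7 in 7 lines, and HES4 was 3036 in TALL-1 and at most 9.6 in 6 lines. DTX1, a NOTCH target, was 4489.8 in KOPT-K1, 2367 in TALL-1 and 1301 in ALL-SIL, and between 18.2 and 32.9 in SKW-3, LOUCY, SUP-T13, DU528, SUP-T11 and HSB-2. IL7R, the interleukin-7 receptor, was 3879 in TALL-1 and 3303 in KOPT-K1 and 15.9 in HSB-2. HES1 was highest in PEER (3327) and lowest in SUP-T11, followed by SUP-T13 (38.1). Of the 14 members 11 had an SD above 1, with a median SD of 1.71 and a median r of 0.296, both at percentile 100. The ACTB 3'/5' ratio related to this list with r = 0.651 (permutation p = 0.00776, adjusted p = 0.089 over 25 lists; rho = 0.765, p = 0.00085; r = 0.711 without JURKAT and MOLT-4).

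The GIMAP genes, a cluster of GTPase genes of lymphocytes, were low together in PF-382, SUP-T11, MOLT-16 and SKW-3, with list values of -2.74, -2.28, -2.06 and -1.78. GIMAP6 was 16.9 in PF-382 and 6769 in HSB-2, GIMAP1 was 15.5 in SUP-T11 and 5823 in PEER, and GIMAP7 was 11.9 in PF-382 and 3497 in PEER. Their median SD was 2.20 and their median r 0.573, both at percentile 100. Genes that TAL1 is known to activate also differed. CDK6 was 10.2 in SUP-T11 and between 6779 and 13685 elsewhere, ETV6 was 28.6 in SUP-T11 and between 658 and 3713 elsewhere, ALDH1A2 was at most 23.1 in 8 lines and 7332 in CCRF-CEM, and ERG was 4092 in LOUCY and 6.2 in ALL-SIL. This list of 14 genes had a median SD of 1.34 and a median r of 0.265 (both at percentile 100). The 11 TAL1 complex partners had 0.62 and 0.194 (both at 99.7). Co-variation of the partners fell to percentile 75.4 without _x_at probe sets and 90.3 with quantile normalization. With the probe set of the highest SD it fell to 87.0, and their spread to 90.7.

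Genes downstream of cytokine receptors were high in a common set of lines. CISH, a feedback inhibitor of STAT5 signalling, was 5856 in HSB-2, 5513 in KOPT-K1, 5436 in ALL-SIL and 3735 in SUP-T13 and at most 446 in 10 lines. PIM1, a kinase gene induced by STAT5, was 5131 in HSB-2, 4540.4 in SUP-T13, 3123 in ALL-SIL, 2626 in DU528 and 1950.0 in KOPT-K1 and at most 372 elsewhere. SOCS1 was 4626 in HSB-2 and SOCS2 8379 in ALL-SIL. The JAK-STAT list of 15 genes had a median SD of 1.09 and a median r of 0.298 (both at percentile 100), with 9 members above an SD of 1. Class I HLA genes, which present antigen, were highest in HSB-2, LOUCY, SUP-T13 and KOPT-K1: HLA-B was 13202, 12725, 11037 and 9075 there and 846 in P12-ICHIKAWA. NLRC5, an activator of class I genes, was 1358 in SUP-T13, 1214 in HSB-2 and 8.4 in SUP-T11, and the peptide transporter TAP1 ran from 281 in SUP-T11 to 2504 in SUP-T13. The 11 class I genes had a median SD of 0.84 and a median r of 0.623 (both at percentile 100). In contrast, 8 of 10 class II genes never reached 4 times the table median, HLA-DPA1 being highest in MOLT-16 (239), and this list's median SD was 0.38 (percentile 59.2; median r 0.062, at 83.5).

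Several tumour suppressor and apoptosis genes were low in 1 or few lines, and others in most. CDKN2A, a cell cycle inhibitor gene often deleted in T-ALL, was 3675 in SUP-T11, 3198 in LOUCY, 2296 in TALL-1 and 1258 in KOPT-K1 and at most 50.8 in the other 12. RB1 was 2.7 in HSB-2, 3.1 in ALL-SIL and 324 in SUP-T11 and between 2169 and 6298 elsewhere. FBXW7, which targets NOTCH1 and MYC for degradation, was 4.1 in PEER and at least 319 elsewhere. EZH2, a histone methyltransferase, was 12.2 in LOUCY and at least 1577 elsewhere. In SUP-T11 both BCL2 (13.9) and PMAIP1 (15.7), which act on opposite sides of apoptosis, were lowest, against 390.1 to 4162 and 1062 to 10838 elsewhere. The 19 suppressor genes had a median SD of 0.58 (percentile 99.9) without co-variation (median r 0.008, percentile 52.7). The 14 apoptosis genes had a median SD of 0.73 (99.8; median r 0.095, 96.4). Their co-variation fell to percentile 83.8 with quantile normalization, 93.2 with centred arrays and 94.9 by rank correlation.

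Proliferation and housekeeping genes were called neither wide nor narrow. MKI67, a marker of dividing cells, lay between 1288 and 4284, MCM5 between 1894 and 5732, and none of the 16 proliferation genes had an SD above 1 (median SD 0.29, percentile 63.7), though they varied together (median r 0.268, percentile 100). Among 10 housekeeping genes the widest was GUSB, from 1501 to 5039. Their median SD of 0.22 lay at percentile 11.1, and their median r of 0.141 at 93.1. Over all 25 lists with at least 5 measured genes, 18 were called wide, 0 narrow and 17 co-varying, which describes these arrays and is not a test.

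**Figure D3:**
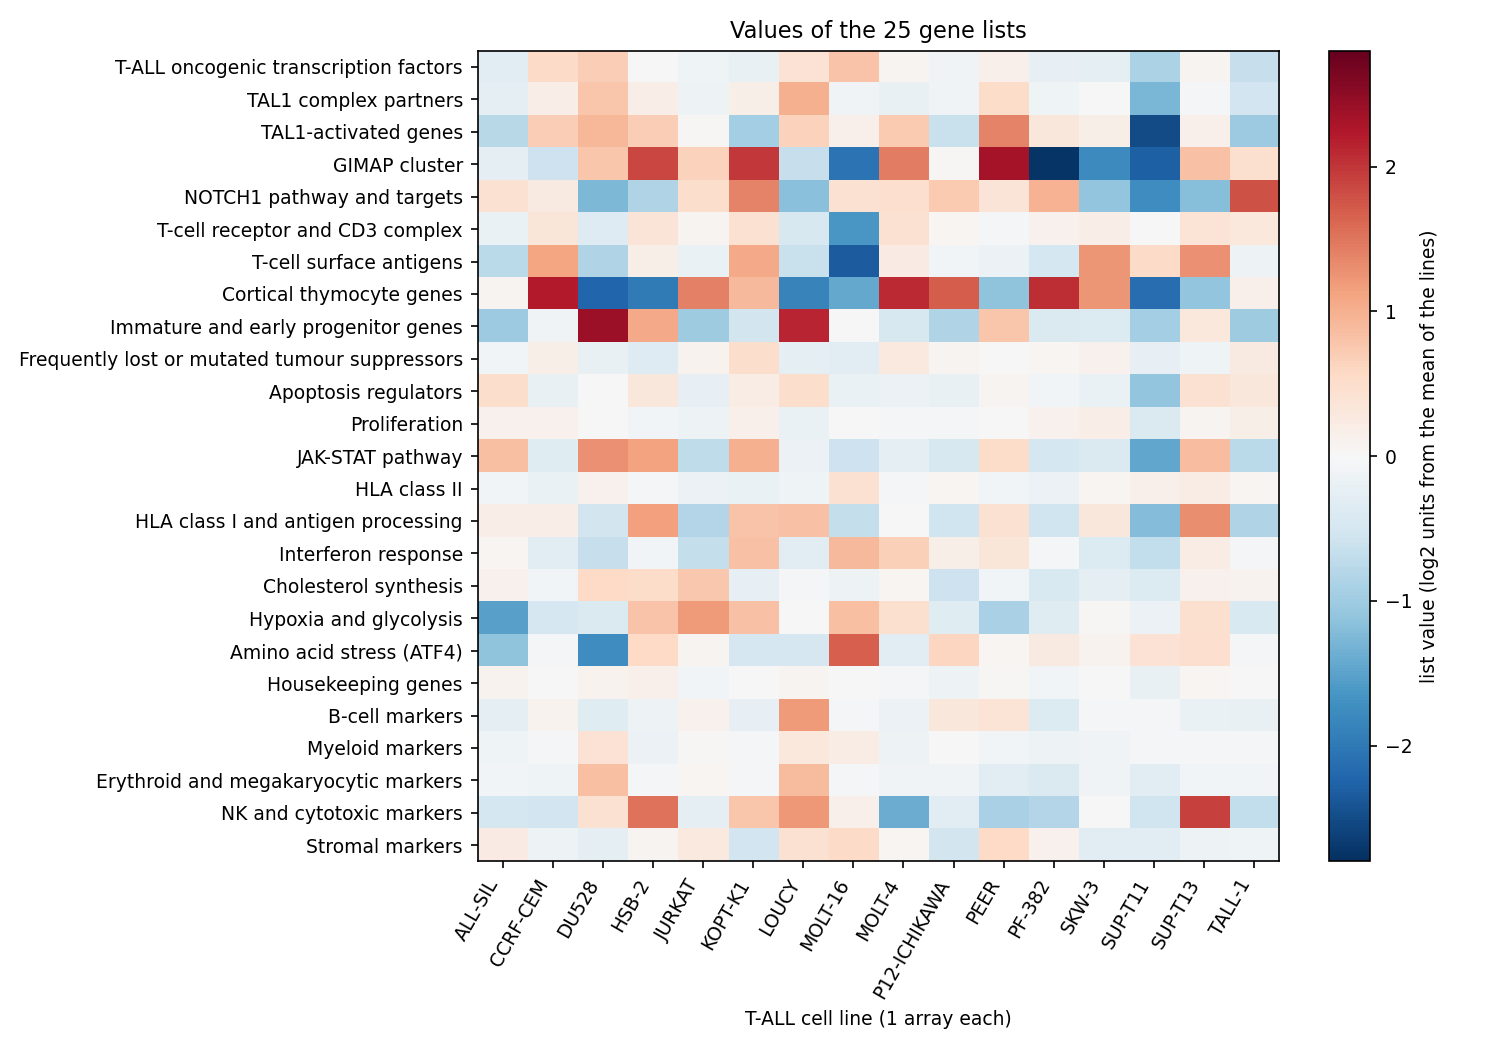
Heat map of 25 gene lists (vertical axis) in the 16 lines (horizontal axis), coloured by the list value, the mean over its genes of the log2 value centred on the gene's mean over lines (log2 units). DU528 and LOUCY are highest for the immature list, and 4 lines are low for the GIMAP cluster.

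Marker genes of other cell types were mostly near background. Of these lists, 6 of 7 myeloid, 4 of 7 B-cell, 3 of 5 erythroid and megakaryocytic and 5 of 8 stromal genes never reached 4 times the table median. Among the others, VIM (3896 to 16200) and CD79A, which lies outside the rule for named genes and was chosen after its values were seen, exceeded it in all 16 lines. Several of the rest were highest in LOUCY or DU528, the lines with the highest immature list values. CD79B, part of the B-cell receptor, was 1152 in LOUCY and 568 in PEER, EBF1 was 865 in LOUCY, the platelet integrin gene ITGA2B was 451 in LOUCY and 353 in DU528, the globin gene HBB was 279.7 and 202.8 in the same lines, and the lysozyme gene LYZ was 384.5 in DU528. SPARC was 2592 in LOUCY and 967 in MOLT-16 and exceeded 4 times the table median in 7 lines, and PDGFRB was 492.5 in ALL-SIL. As reported, neither spread nor co-variation of these 4 lists passed percentile 95. Their median SDs were 0.27 (myeloid, percentile 17.2; median r -0.053, at 23.7), 0.40 (B-cell, 55.7; 0.124, at 92.4), 0.46 (erythroid and megakaryocytic, 73.6; 0.056, at 68.1) and 0.37 (stromal, 55.7; 0.096, at 90.6). Cytotoxic genes differed from these. GZMA was 15841 in LOUCY and 7315 in MOLT-16, NKG7 was 4915 in SUP-T13 and 3499 in HSB-2, GNLY was 1777 in HSB-2, and PRF1, perforin, was 1364 in DU528. This list had a median SD of 1.36 (percentile 99.9) and a median r of 0.241 (99.8). By rank correlation its co-variation fell to percentile 80.9.

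Planned relations asked whether the level of a gene or a list followed that of related genes, which were not always its targets. LYL1, a relative of TAL1 expressed in progenitors, was higher in lines with higher immature genes (r = 0.826, permutation p = 0.00021, adjusted p = 0.00147; rho = 0.797, p = 0.00037). DTX1 followed the other NOTCH1 pathway genes (r = 0.926, permutation p = 2e-05, adjusted p = 0.00021; rho = 0.832, p = 0.00016). NLRC5 followed the class I genes (r = 0.927 with rho = 0.906, each with a permutation p of 1e-05, the smallest that the permutations can give, and an adjusted p of 0.00021). Without the 2 lines farthest from the median of the first measure, r was 0.659 for LYL1 (without DU528 and LOUCY), 0.908 for DTX1 (without KOPT-K1 and TALL-1) and 0.942 for NLRC5 (without MOLT-16 and SUP-T11). All tests were two-sided, and the adjusted values cover 21 tests, of which these 3 passed 0.05. The adjusted p of rho was 0.00259, 0.00168 and 0.00021.

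With the ACTB 3'/5' ratio taken out of both measures, r was 0.715 for LYL1 (adjusted p = 0.00715), 0.871 for DTX1 (adjusted p = 0.000165) and 0.909 for NLRC5 (adjusted p = 0.00011). Levels of DTX1 left a gap of 25.9% of their range, under the third of the range that counted as a split. Among the 6 lines below that gap r was 0.372 (exact p = 0.376; rho = -0.143, p = 0.803), and among the 10 above it 0.719 (permutation p = 0.0171; rho = 0.552, p = 0.106). In the 6 lines below, DTX1 lay between 18.2 and 32.9, under the table median, so r there can say little about a relation. For NLRC5 the 8 lines below its largest gap gave r = 0.562 (exact p = 0.149; rho = 0.405, p = 0.327) and the 8 above it 0.883 (exact p = 0.00437; rho = 0.833, p = 0.0154). For LYL1 the 10 lines below gave r = 0.67 (permutation p = 0.0364; rho = 0.309, p = 0.385) and the 6 above 0.881 (exact p = 0.0222; rho = 0.886, p = 0.0333).

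**Figure D4:**
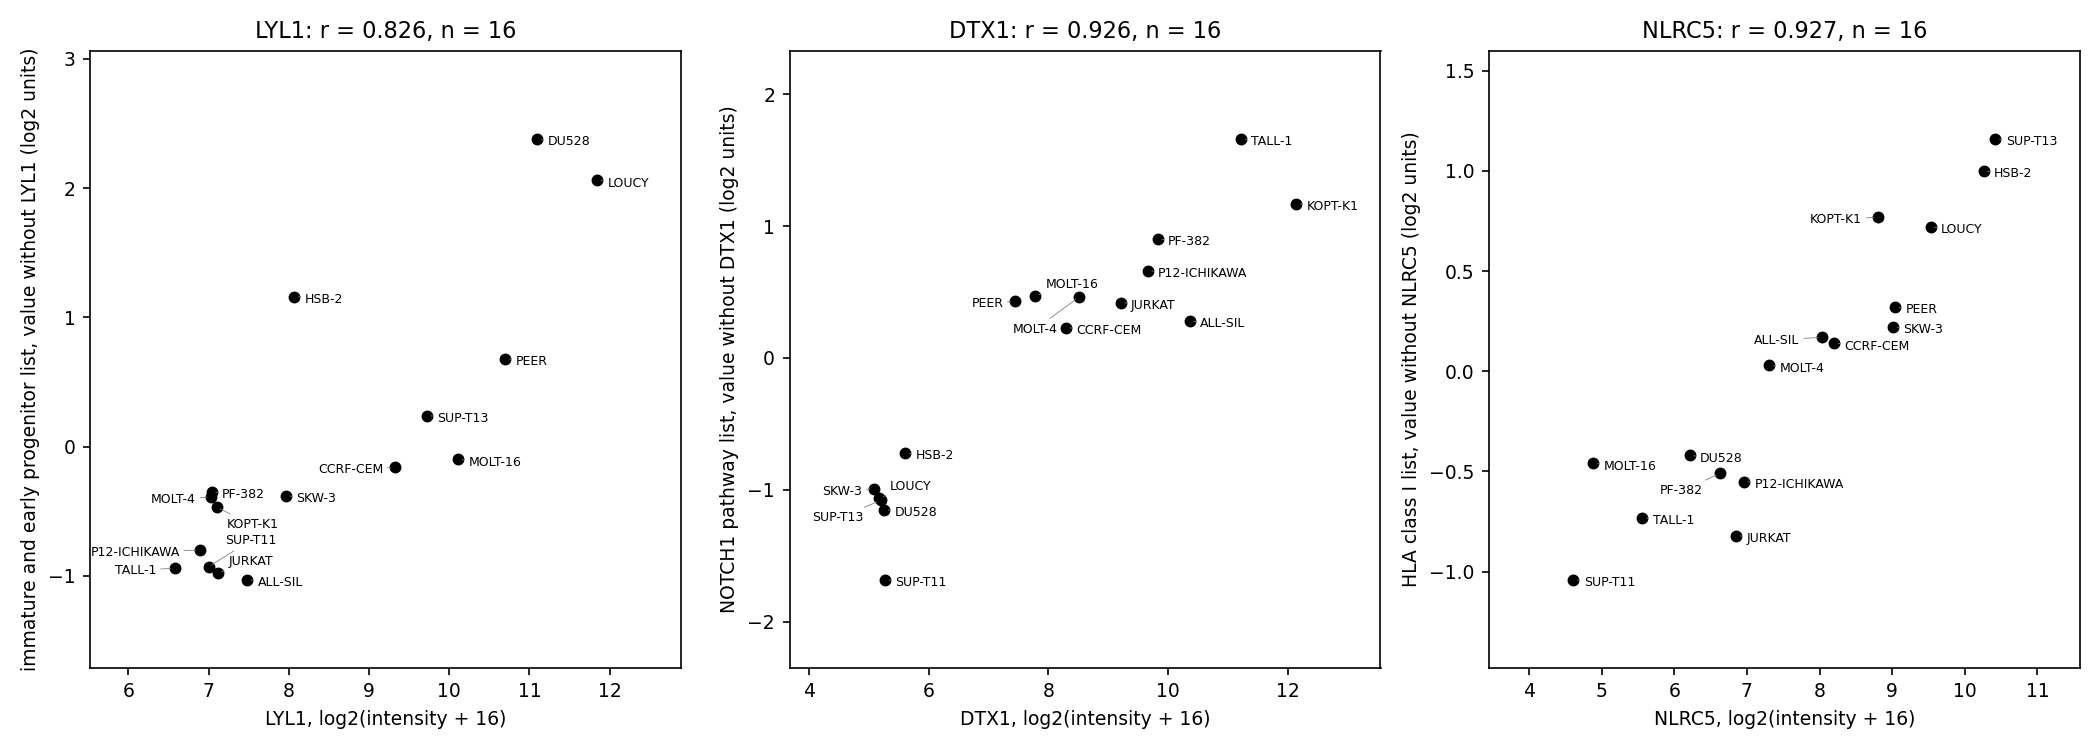
Scatter plots of 3 genes, LYL1, DTX1 and NLRC5 (horizontal axes, log2(intensity + 16)), against the value of the list each was paired with (vertical axes, log2 units), 1 point per line. The list value is higher where the gene is higher, with r of 0.826, 0.926 and 0.927.

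The relation of cortical to immature genes did not pass the threshold (r = -0.609, permutation p = 0.0111, adjusted p = 0.0583; rho = -0.45, p = 0.0828; r = -0.699 without DU528 and SUP-T11). It passed without SUP-T11 (r = -0.753, adjusted p = 0.00241) or without CCRF-CEM (r = -0.641, adjusted p = 0.0432), and with log2(value + 64), centred arrays, the mean of all probe sets or the probe set with the highest SD. Its r was -0.322 with the ACTB ratio taken out. T-cell receptor and cortical genes had r = 0.441 (permutation p = 0.0657, adjusted p = 0.234; rho = 0.5, p = 0.0506; r = 0.384 without LOUCY and MOLT-16). With the ACTB ratio taken out they passed the threshold by r (0.629, permutation p = 0.0118, adjusted p = 0.0324) but not by rho (p = 0.0773), and r was 0.273 without the 2 farthest lines. CDKN2A and its neighbour CDKN2B had r = -0.537 over the 12 lines with low CDKN2A (permutation p = 0.0669, adjusted p = 0.234; rho = -0.462, p = 0.133; r = -0.649 without CCRF-CEM and P12-ICHIKAWA). In these lines CDKN2A lay between 8.3 and 50.8 and CDKN2B between 10.9 and 44.0, near background, so this r is not taken to show a relation. LMO2 and the immature genes had r = 0.041 over the 12 lines that expressed LMO2 (permutation p = 0.901, adjusted p = 0.926; rho = -0.084, p = 0.801), against 0.813 without KOPT-K1 and P12-ICHIKAWA (adjusted p = 0.0373), the lines with the highest LMO2. MYC followed neither the NOTCH1 genes (r = 0.203, permutation p = 0.503, adjusted p = 0.765; rho = 0.171, p = 0.524; 0.094 without LOUCY and MOLT-16) nor the proliferation genes (r = 0.346, p = 0.0979, adjusted p = 0.294; rho = 0.182, p = 0.496; 0.223 without the same lines).

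Because TAL1 split the lines, its relations were tested within the 8 lines with high and the 8 with low TAL1. None of its 3 list relations passed in either set, and the largest r with all lines of a set kept was 0.581 with the GIMAP genes in the high set (exact p = 0.127, adjusted p = 0.334; rho = 0.571, p = 0.151; 0.599 without JURKAT and MOLT-16). The TAL1-activated genes gave r = 0.05 in the high set (exact p = 0.923, adjusted p = 0.926; rho = 0.143, p = 0.752; 0.653 without JURKAT and MOLT-16) and 0.568 in the low set (exact p = 0.149, adjusted p = 0.347; rho = 0.595, p = 0.132; -0.004 without DU528 and PEER), so both depended on 2 lines. Against single genes, 0 of 60 exact two-sided tests passed an adjusted p of 0.05 and 6 had an unadjusted p below 0.05, with the same count of 0 for rho. LMO2 was lower where TAL1 was higher in the high set (r = -0.856, exact p = 0.00841, adjusted p = 0.396; rho = -0.762, p = 0.0368), but r was -0.229 without JURKAT and MOLT-16. KIT was higher where TAL1 was higher in the low set (r = 0.835, exact p = 0.0137, adjusted p = 0.396; rho = 0.881, p = 0.00724), and r was 0.511 without DU528 and PEER. CDK6 gave r = 0.755 in the high set with or without JURKAT and MOLT-16 (exact p = 0.0243, adjusted p = 0.396; rho = 0.786, p = 0.0279). Levels of TAL1 in the low set lay near background, and DU528, the line at their upper end, is the line in which the TAL1 probe sets differed. On the second probe set DU528 (373.6) lay above all 8 high lines, and no relation was tested with DU528 among them.

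The genes that followed LYL1 over the 16 lines were sought with limma. CD93, a receptor of endothelial and myeloid cells, was higher with higher LYL1 by 1.16 ± 0.12 log2 units per log2 unit of LYL1 (SE, adjusted p = 0.000301), as were SLC39A3 (0.40 ± 0.05, adjusted p = 0.000936) and the haematopoietic homeobox gene HHEX (1.40 ± 0.21, adjusted p = 0.0092). HDAC4, a histone deacetylase, was lower with higher LYL1 (-0.57 ± 0.09, adjusted p = 0.0092), as were ZNF346 (-0.30 ± 0.05, adjusted p = 0.0108) and KPNA5 (-0.26 ± 0.04, adjusted p = 0.0111). In all 112 of 13306 genes passed an adjusted p of 0.05, 87 with and 25 against LYL1. Of 12 immature genes tested 3 passed over all genes and 5 adjusted over the list alone (HHEX, GATA2, MEF2C, NFE2 and IGFBP7). Of 12 cortical genes 0 passed over all genes and 5 adjusted over the list alone, all lower with higher LYL1 (BCL11B, CD1A, CD1B, CD1D and CD1E). Of 14 TAL1-activated genes 0 passed over all genes and 6 adjusted over the list alone, 5 with and 1 against LYL1. Calls over a list alone were not adjusted across lists and were not repeated without DU528 and LOUCY. Of all 13306 genes, 2085 had an unadjusted limma p below 0.05. Among 100 permutations of the LYL1 levels the highest count of genes passing an adjusted p of 0.05 was 2. The ACTB 3'/5' ratio was not taken out of this fit, and permuting LYL1 cannot test its part. That ratio was lowest in DU528 (1.44) and LOUCY (1.45), the lines with the highest LYL1. It was next lowest in SUP-T13 (1.453) and PEER (1.503), where LYL1 was 829.1 and 1651.7. In CCRF-CEM and MOLT-16, the other lines above the largest gap in LYL1, the ratio was 1.627 and 1.90, with LYL1 at 622.2 and 1085. The count was 67 with log2(value + 1) and 63 without a filter on low genes. Leaving out 1 line moved the count to 11 without LOUCY, 33 without DU528, 35 without PF-382, 38 without KOPT-K1, 46 without MOLT-4, 48 without P12-ICHIKAWA, 64 without TALL-1 and 66 without CCRF-CEM, and 1 gene passed without both DU528 and LOUCY.

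For MYC the same model called 102 genes, 41 with and 61 against MYC. ATP11B, a lipid flippase (0.71 ± 0.05 log2 units per log2 unit of MYC, SE, limma adjusted p = 4.17e-07), TFDP1, a partner of E2F factors (0.90 ± 0.07, adjusted p = 2.79e-06), EZH2 (0.88 ± 0.07, adjusted p = 2.79e-06) and the cyclin gene CCNC (0.81 ± 0.07, adjusted p = 4.29e-06) were higher with MYC. TSC22D3 (-0.42 ± 0.05, adjusted p = 0.000121) and HOXB9 (-0.39 ± 0.05, adjusted p = 0.000187) were lower. This count rested on LOUCY, the line with low MYC: 0 genes passed without it, and 12 of 100 permutations gave a count as large, the highest being 367. It was 203 without a filter on low genes, 57 with a mean above the table median and 56 with the mean of all probe sets. In LOUCY, MYC (23.6), ATP11B (23.6), TFDP1 (19.4), EZH2 (12.2) and CCNC (39.0) all lay under the table median. The slopes of these genes thus set 1 line near background against the rest and are not taken to show genes that follow MYC. Among 18 tumour suppressor genes 2, EZH2 and USP7, passed over all genes and 2 adjusted over the list alone. Among 13 immature genes 0 passed over all genes and 2 adjusted over the list alone (MEF2C and GATA2, against MYC).

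TAL1 levels within the 8 lines with high TAL1 were followed by 0 genes in limma at an adjusted p of 0.05, with 775 of 13306 at an unadjusted p below 0.05 and a smallest adjusted p of 0.675. Adjusted over the list alone, without adjustment across lists, 3 of 9 cholesterol synthesis genes passed (SQLE, HMGCS1 and FDPS, higher with TAL1). LMO2, lower with TAL1, and ADM of the hypoxia list, higher with TAL1, also passed. JURKAT, with the highest TAL1, was the highest line for SQLE, HMGCS1 and FDPS. MOLT-16, with the lowest TAL1 of this set, was the lowest of the set for the same genes. ADM was 206.9 in JURKAT, 55.4 in MOLT-4 and 8.1 to 22.5 in the rest of the set. The list calls were not repeated without JURKAT and MOLT-16, and r of LMO2 was -0.229 without them. Within the 8 lines with low TAL1, 71 genes passed, 43 with and 28 against TAL1. TAL1 was 14.7 to 24.8 in 7 of these lines, under the table median, and 48.5 in DU528, the line whose TAL1 probe sets differed, so slopes per unit of TAL1 are not given and the count is not taken to show genes that follow TAL1. This second count was 0 without DU528, 33 without TALL-1, 37 without P12-ICHIKAWA, 42 without KOPT-K1 and 116 without PEER, and 1 of 100 permutations gave as many.

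Across all genes the spread between lines was wide for a minority. BEX3 had the largest SD, 3.93, with 9239 in LOUCY and 8.1 in SUP-T13. GTSF1 (SD 3.65) was 9228 in PEER and 8.5 in LOUCY, LGALS1, galectin-1 (3.59), was 13809 in LOUCY and 10.3 in PF-382, LAPTM4B (3.52) was 5556 in LOUCY and 2.9 in ALL-SIL, and MDFIC (3.21) was 6813 in ALL-SIL and 5.4 in MOLT-4. APP, the amyloid precursor gene (3.19), was 10404 in TALL-1 and 1.9 in LOUCY, and HOXB2 (3.18) was 4091 in LOUCY and 6.5 in PF-382. Of 19740 genes, 2464 had an SD above 1 and 2079 a range of at least 4 log2 units, and the median SD was 0.35. With log2(value + 64) the counts fell to 1517 and 1043, and with the mean of all probe sets 1327 genes had such a range.

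Many genes set a single line apart. DU528 was far above every other line in SERPIND1, a thrombin inhibitor (3751 against at most 12.9), CLCA1 (4973 against 32.5) and HOPX (2539 against 26.5). So was SUP-T11 in the neuronal hydrolase gene UCHL1 (3669 against 60.5) and PEG3 (1534 against 28.6), LOUCY in FKBP10 (2543 against 39.6) and HOXB8 (1639.9 against 24.7), HSB-2 in the cytochrome gene CYP1B1 (6209 against 148), PEER in PRSS3 (1331 against 24.5) and SUP-T13 in the growth factor receptor PDGFRA (973 against 18.6). Other genes were low in 1 line alone. The lines and their genes included SUP-T11 with ARID1A, a chromatin remodeller (4.83 against at least 2772), HSB-2 with the mismatch repair gene MSH6 (5.75 against 2098), LOUCY with TFDP1 (19.4 against 2371), DU528 with PHGDH, the first enzyme of serine synthesis (23.5 against 2369.9), TALL-1 with YBX3 (7.86 against 3905), and PF-382 with the cytokine gene IL32 (4.12 against 306). The size rule asked for a gap of at least 3 log2 units for high and 2 for low genes, so high and low counts cannot be compared directly. It found 102 genes set apart high and 255 set apart low, against 60 and 131 with log2(value + 64), and 151 low with the mean of all probe sets. SUP-T11 had 22 high and 53 low, DU528 25 and 36, LOUCY 19 and 17, ALL-SIL 1 and 33, TALL-1 1 and 37 and MOLT-16 4 and 27, while CCRF-CEM had 0 and 1. With 1 array per line this rule has no replicate check.

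**Figure D5:**
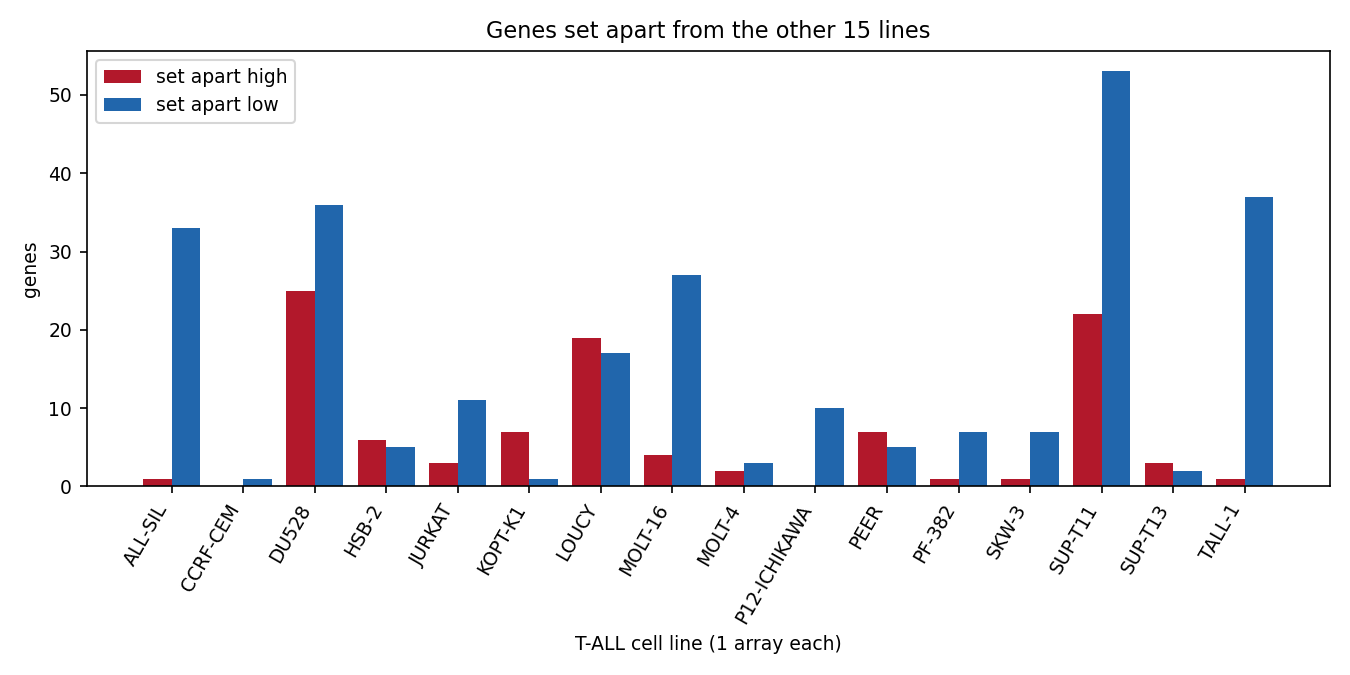
Number of genes (vertical axis) set apart high or low in each of the 16 lines (horizontal axis), as bars from 0. SUP-T11 and DU528 have the most genes set apart, with 53 and 36 low. The gap asked for was 3 log2 units for high and 2 for low genes, so the 2 kinds of bar cannot be compared directly.

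Over the 1000 genes with the highest SD, MOLT-4 and PF-382 were the most alike (r = 0.673 across genes, which are not independent replicates) and DU528 and PF-382 the least (r = -0.052). The median r over all pairs of lines was 0.291. HSB-2 and SUP-T13 had r = 0.564 and CCRF-CEM and PEER 0.592, whereas SUP-T11 resembled no line closely (0.25 to its closest line, PF-382). The first principal component held 17.0% of the variance and ran from DU528, LOUCY and HSB-2 (scores 81.9, 56.7 and 54.7) to TALL-1 and P12-ICHIKAWA (-46.4 and -44.3), and the third, with 10.5%, set SUP-T11 apart (110.9 against at most 9.83).

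Along the first component 5 of 25 lists varied, in a family of 50 two-sided permutation tests with the second component, which 0 lists followed. Immature genes were higher toward DU528 (r = 0.896, permutation p = 1e-05, the smallest possible, adjusted p = 0.0005; rho = 0.776, p = 0.0006; r = 0.793 without DU528 and LOUCY). So were cytotoxic genes (r = 0.693, p = 0.00337, adjusted p = 0.039; rho = 0.559, p = 0.0269; r = 0.722). Cortical genes (r = -0.766, p = 0.00057, adjusted p = 0.0142; rho = -0.741, p = 0.0016; r = -0.691), NOTCH1 pathway genes (r = -0.738, p = 0.00109, adjusted p = 0.0182; rho = -0.865, p = 5e-05; r = -0.672) and tumour suppressor genes (r = -0.681, p = 0.0039, adjusted p = 0.039; rho = -0.724, p = 0.00241; r = -0.639) were lower. The calls depended on the constant added before the log: with log2(value + 1) 3 lists followed the component, tumour suppressor (r = -0.66, adjusted p = 0.0529) and cytotoxic genes (r = 0.664, adjusted p = 0.0529) losing their calls, and with log2(value + 64) 8 did, with housekeeping, myeloid and erythroid and megakaryocytic genes added. Tumour suppressor genes also lost theirs with the mean of all probe sets (adjusted p = 0.0584) or the probe set with the highest SD (adjusted p = 0.0931). With the latter probe set, myeloid (adjusted p = 0.0387) and erythroid and megakaryocytic genes (adjusted p = 0.0465) gained calls. Erythroid and megakaryocytic genes also gained one without a filter on low genes (adjusted p = 0.0475). Among 10 tests of technical measures, the ACTB 3'/5' ratio followed the same component (r = -0.736, permutation p = 0.0013, adjusted p = 0.013; rho = -0.791, p = 0.00045; r = -0.645), as did the hybridisation controls (r = 0.681, p = 0.00322, adjusted p = 0.0161; rho = 0.511, p = 0.0449; r = 0.478). With the ACTB ratio taken out, 1 list, the immature genes, followed it (r = 0.821, adjusted p = 0.003), and without SUP-T11 8 lists did.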

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

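Quantile normalization and array centring, taking out the ACTB ratio, leaving out SUP-T11 from the components, leaving out each line from the spread and the set-apart genes, and both sides of the largest gap were chosen after seeing the data. Over all alternatives, planned or added, r kept its sign in the 3 planned relations that passed as reported, though rho of DTX1 was -0.143 in the lines below the largest gap, and r changed sign in some relations that had not passed. Of 315 alternative counts and summary values for 18 results, 266 were within their limits, 41 moved, 4 crossed upward and 4 downward. Of 813 alternative r values for 31 relations, 801 kept their side of the threshold, 10 came to pass it and 2 lost it. The last 2 were DTX1 (0.372) and NLRC5 (0.562) in the lines below the largest gap, where DTX1 lay under the table median. P-values on the sides of a gap were not adjusted, and that of LYL1 below its gap was 0.0364 by permutation. Of 199 spread percentiles 192 and of 224 co-variation percentiles 212 kept their side. Those that changed were of the TAL1 partner, apoptosis, cholesterol, cytotoxic, HLA class II, stromal, B-cell and housekeeping lists. Where thresholds were changed, the construction shows the cause, and elsewhere, also where lines were left out, the cause was not tested.

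With log2(value + 64), 1517 genes had an SD above 1, 1043 a range of at least 4, 60 were set apart high and 131 low, 8 lists followed component 1 and 2 followed component 2, and 108 genes followed TAL1 in the lines with low TAL1. With log2(value + 1), 3 lists followed component 1, 37 genes followed TAL1 there and 67 followed LYL1. With the mean of all probe sets, 1327 genes had a range of at least 4, 1 list, the housekeeping genes, was narrow (percentile 2.9), 151 genes were set apart low, 36 followed TAL1 in the low lines and 56 followed MYC. Without _x_at probe sets 46 genes followed TAL1 there. By the probe set with the highest SD, and likewise with quantile normalization, 1 list followed component 2. Without a filter on low genes 108 genes followed TAL1 in the low lines, 63 LYL1 and 203 MYC, and with a mean above the table median 57 followed MYC. An SD threshold of 1.5 left 1227 genes. Smaller gaps (2 log2 units high, 1.5 low) gave 298 high and 386 low genes, and larger gaps (4 high, 3 low) 30 and 123. At an equal gap of 2 there were thus 298 high and 255 low genes, and at 3 there were 102 and 123. Over 5000 genes the highest r between lines was 0.846 and the lowest 0.492. With the ACTB ratio taken out 1 list followed component 1, and without SUP-T11 8 did.

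Without the 2 lines farthest from the median, 5 planned relations passed, and 0 genes followed TAL1 in the low lines, 1 LYL1 and 0 MYC. Leaving out each line in turn gave 0 to 116 genes for TAL1 in the low lines (lowest without DU528, highest without PEER), 11 to 148 for LYL1 (without LOUCY, without MOLT-16) and 0 to 127 for MYC (without LOUCY, without SUP-T11), and 3 to 4 planned relations. For TAL1 in the high lines it gave 0 genes each time. Intensities near or under the table median of 42.3 were treated as background, which limits comparisons between lines at such levels.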

Other observations

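Genes of metabolism and stress varied in sets of lines. PSAT1, an enzyme of serine synthesis, was 4.9 in DU528, 8.5 in LOUCY, similarly low in ALL-SIL and TALL-1, and between 1939 and 10856 elsewhere, and ASNS, asparagine synthetase, was 24.4 in DU528, 43.2 in LOUCY and 5976 in MOLT-16. CHAC1, a target of the stress factor ATF4, was 1053 in MOLT-16 and 2.0 in LOUCY. Of the 12 genes of the ATF4 list 8 had an SD above 1, with a median SD of 1.31 (percentile 99.9; median r 0.186, also at 99.9). Among hypoxia and glycolysis genes, BNIP3 was 5156 in MOLT-16 and 4796 in JURKAT and at most 17.5 in PEER, LOUCY, TALL-1 and ALL-SIL, PDK1 was 2.9 in ALL-SIL and at least 446 elsewhere, and VEGFA was 2266 in TALL-1 and 9.4 in ALL-SIL (12 genes, median SD 1.28, median r 0.304, both at percentile 100). Cholesterol synthesis genes varied together. HMGCS1 ran from 1598 in P12-ICHIKAWA to 5052 in JURKAT, and the 9 genes had a median SD of 0.54 (percentile 97.8) and a median r of 0.5 (percentile 100). The proliferation and cholesterol lists were not related (r = -0.07, permutation p = 0.799, adjusted p = 0.926 over 21 tests; rho = -0.147, p = 0.587; r = -0.483 without LOUCY and SUP-T11).

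Interferon response genes were high in different lines. MOLT-16 had the highest IFIT3 (2305), IFIT1 (1012) and IFIT2 (1316), HSB-2 the highest MX1 (1187) and KOPT-K1 the highest IFI6 (4063). DU528 had the lowest MX1 (7.2), IFI44 and IFI6 (493). The 11 genes had a median SD of 0.98 (percentile 98.3) and a median r of 0.129 (percentile 98.7), and the 19 transcription factors 0.58 (percentile 99.9) and 0.022 (percentile 77.8).

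For the patterns below, the tests of neighbouring genes, of genes of the same level and of the ACTB ratio were chosen only after the result was seen, and since the labels form no groups of lines, loss of neighbouring genes was the only biological explanation tested.

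TAL1 probe sets in DU528 differed: 48.5 on the probe set used and 373.6 on the second, 3.22 log2 units off the trend that held over the other 15 lines (r = 0.976, across lines). If probe sets of a gene differed in general on the DU528 array, such a residual would be common, but 0.03% of 2876 other probe set pairs (1 pair) had one as large, and the median absolute residual was 0.198. This argues against a fault of the array as a whole. Cross-hybridisation of the second probe set to another transcript was not tested and stays open, as does a TAL1 transcript that the first probe set misses.

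Of the 255 genes that were low in 1 line alone, SUP-T11 had the largest count of any line (53), followed by TALL-1 (37), DU528 (36) and ALL-SIL (33). A lower response of the array would act alike on genes of 1 level, whatever the scaling. The low genes fell by a median of 4.52 log2 units, which depends on the added constant because many of them reached background in that line. Of the 100 genes nearest to each in mean level, a median of 2.0% (at most 23.0%) fell by 50% of that gene's log2 fall or more in the same line. This argues only against a lower response shared by genes of 1 level. Array medians lay between 37.6 and 45.0, so a shared fall of that size could hardly have been found on any array. Smaller array effects were not tested. Faulty single probe sets do not account for most of those with a second usable probe set, since in 137 of 154 such genes (89.0%, 95% Clopper-Pearson interval 82.9 to 93.4, chance 6.25) that probe set was lowest in the same line. In all, 14 pairs of low genes lay within 10 genes of each other in the same line. In 10000 shuffles of the line names the median was 4.0 (1 as large, p = 0.0002). By the same shuffles the 10 pairs whose names do not begin alike gave p = 0.005. Loss of neighbouring genes together may account for some of the low genes. The shuffles cannot tell such loss from other causes that lower neighbouring genes together. The pairs, named after their values were seen, include MSH6 and FBXO11 in HSB-2, PHGDH and NOTCH2 in DU528, BCL2 and PMAIP1 in SUP-T11 and SMIM30 and TMEM168 in ALL-SIL, and no DNA data were used here.

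The first component ran with the ACTB 3'/5' ratio, so RNA integrity could contribute to the lists along it. For the immature genes r with the component was 0.896 and 0.821 (adjusted p = 0.003) once the ratio was taken out of both, which argues against the ratio as the whole cause. For the other 4 lists the absolute r was 0.681 to 0.766 before and 0.479 to 0.54 after (median 0.526, smallest adjusted p = 0.105), so for the cortical, NOTCH1, tumour suppressor and cytotoxic genes RNA integrity and other differences between the lines cannot be told apart with 1 array each. The calls ended because these r values fell, with 16 lines in each test. The hybridisation controls, which also followed the component (r = 0.681), were not taken out, so their part was not tested for any list. The GAPDH ratio had r = -0.097 with the component (permutation p = 0.724, adjusted p = 0.804 over 10 tests; rho = -0.194, p = 0.467; r = -0.061 without DU528 and LOUCY).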
